A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

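The study measured messenger RNA in a haploid w303 strain of budding yeast (Saccharomyces cerevisiae, mating type a) grown in defined glucose medium. Per the labels, 3 libraries came from log-phase cultures at 30.0 °C, 3 from log-phase cultures at 39.1 °C and 2 from cultures at 40.5 °C called no-growth, whose density the labels give as rising from 48000 to 400000 cells/mL. The labels call the libraries biological replicates and give replicate numbers. Libraries were made with a kit that primes at the 3′ end of messenger RNA (QuantSeq), per the labels' protocols. TopHat2, Cufflinks and Cuffdiff and the genome build R64 are named in the submitters' processing notes, and their versions and settings are not given in the sources used here.

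The single table holds FPKM values (fragments per kilobase of transcript and mapped fragments) that the authors computed and deposited as 1 value per temperature, with the lower and upper bound of an interval and a status, per the file headers. The level of that interval is not stated. The bounds lie at equal distances from the value unless the lower one ends at 0. Columns were assigned to the 3 temperatures by the codes they share with the library titles. The codes of the hot cultures, 390 and 400, differ from the 39.1 °C and 40.5 °C that the labels state for those libraries; the stated temperatures are used here. No column holds a single library, so the spread between libraries could not be computed, and every value is the authors' pooled value with no SD and no n. The planned linear model on single libraries could not be fitted for the same reason, and the rule written for pooled columns was used. A 3′-end library gives reads from 1 end of a transcript, and FPKM divide by transcript length. Levels of genes of different length are therefore not on 1 scale. The ratio of 1 model between temperatures is less affected, but a shift of reads between transcripts or models that share them can still alter it.

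The table has 7025 gene models, all with status OK. Of these, 6524 carry 1 gene name, 416 carry several names and 85 carry none; 6061 of 7067 distinct names were found in the R64 annotation, and all models lie inside the chromosome lengths of R64. Names stand alone in 2 or more models in 308 cases, and these models were kept apart. The models share 805 locus intervals, and up to 605 models share 1 of them. The median locus is 1.41 kb wide, but the median model lies in a locus of 588 kb; how these loci arose is not given in the sources used here. Loci under 10 kb are called narrow here and hold 1065 models. Among the 826 narrow models with 1 name found in R64, the locus contains the named gene in 822. No column gives the strand. Model numbers follow position along chromosome IV and then start again at lower positions. They may reflect strand, which was not examined, so a gene and its antisense transcript were not told apart here. Models with several names hold reads of more than 1 gene. Near-identical copies, such as pairs of ribosomal protein genes and the TDH, HXT, EFT and COS families, can share reads, so their values are uncertain.

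The authors' intervals are much narrower in narrow loci. At 30.0 °C the median half-width was 59.2% of the FPKM among tested models in narrow loci and 634% in wide loci, where 96.2% of lower bounds were 0. Sequencing depth is unknown. The lowest values were compared with whole multiples of the smallest one: 20% lay within 0.05 of a multiple at 30.0 °C, 10% at 39.1 °C and 7% at 40.5 °C, against 10% by chance, so no read size could be recovered. FPKM summed to 6370181.5 at 30.0 °C, 5018383.7 at 39.1 °C and 3694616.5 at 40.5 °C. The ribosomal RNA model RDN37-1 held 14.6%, 22.2% and 12.5% of these sums.

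A model was tested when its mean over the 3 temperatures was at least 5 FPKM, which left 5056 models, 689 of them in narrow loci. A model was called higher or lower when the authors' intervals at both temperatures did not overlap and the ratio of (FPKM + 1) was at least 2-fold; no p-value was computed. Log2 ratios are of FPKM with a pseudocount of 1, which understates changes of low genes. Their standard errors come from the intervals by the delta method, with the half-width taken as 2 SD, an assumption. An exact 0 may be a failed estimate in such a table, and the authors give it an interval of no width: where a value is 0, the gene is said to be listed at 0 and no ratio is given.

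Before the data were examined, 33 gene lists were fixed. For each list the median log2 ratio of its models with 1 name was set against 10000 random lists of the same size, drawn from tested models with 1 name and matched in 10 classes of mean level. A list lay above or below when its median passed the 97.5th or fell under the 2.5th percentile; this describes these pooled values and is not a test across replicates. Lists with fewer than 3 measured models were left out, which removed the alpha-cell genes and the mitochondrially encoded genes. Also fixed beforehand was the rule for named genes. It takes the 8 largest rises and the 8 largest falls among called models of each comparison, up to 4 members with the largest ratios and the most abundant member of each described list, and GSH1, GSH2, GLR1, HSP104, SSA4, HSP26, HSP12, CTT1, SOD1, SOD2, TSA1, TRX2, CLN2, HTA2 and RPL3. Other called members of the lists are named as well, as are KRI1, MRF1, YOR283W, EFT2 and the models of the closing section; these were chosen after their values were seen. Some genes that the rule selects are not reported here.

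The calling rule was tested on simulated data before use: 200 of the models eligible at 30.0 °C were changed in each of 50 simulations, within the authors' intervals. A 4-fold change was called in 53.3% of narrow models and 3.85% of wide ones, and an 8-fold change in 66.1% and 5.60%. Of unchanged models 0.281% in narrow loci and 0.0343% in wide loci were called. The simulated noise and intervals both came from the authors' half-widths, taken as 2 SD. These rates therefore hold no spread between cultures beyond those intervals and are not error rates for real cultures. The list method was tested on ratios drawn independently at SD 1, not from the intervals. Among 100 such lists of 30 unchanged models, 3% lay outside the central range, and 99% of 100 lists moved by 1 on the log2 scale did. These rates need not hold for the real lists. In wide loci the median standard error was 6.52 at 39.1 °C against 30.0 °C, and models share loci. Alternatives changed the pseudocount, the filter on low values, the scaling, the fold minimum and the use of the intervals, among them a z test of the log2 ratio with the standard error above, adjusted over all tested models by the method of Benjamini and Hochberg. Added after the data were seen were runs on narrow loci, on models with 1 name, without models listed at 0, and with other ways to build the lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.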

Results

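Yeast messenger RNA was measured at 3 temperatures: 30.0 °C, the usual growth temperature, 39.1 °C, and 40.5 °C, where the labels speak of log-phase growth at the first 2 and of no growth at 40.5 °C. The 30.0 °C cultures (3 libraries) were taken in log phase at about 1200000 cells/mL. The 39.1 °C cultures (3 libraries) started at about 10000 cells/mL and reached 1200000 cells/mL after about 3 days in 1 culture and 1700000 cells/mL after about 4 days in the others. The 40.5 °C cultures (2 libraries) started at about 48000 cells/mL and stood at about 400000 cells/mL after about 3 days, so their density rose although the labels call them no-growth cultures. The deposited values are the authors' pooled FPKM, 1 per gene and temperature, with the authors' interval; no library has a value of its own. All differences below therefore have no replicate check, and depth is unknown. Culture time at 30.0 °C is not given in the labels.

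The first comparison asked how cells growing near their upper temperature limit differed from cells at 30.0 °C. Of 5056 tested gene models, 38 were higher and 46 lower at 39.1 °C. The largest fall was that of ZPS1 (chromosome XV, 34658 to 35407), a gene of the zinc-starvation response, from 3694 FPKM (authors' interval 2824 to 4564) to 39.9 FPKM (16.8 to 63.1), a log2 ratio of −6.50 ± 0.44 (SE). The alcohol dehydrogenase gene ADH4 (chromosome VII, 15159 to 16307) went from 1069 FPKM (815 to 1322) to 134 (95.5 to 172), and a model that holds the zinc transporter gene ZRT1 with 4 other genes went from 9553 FPKM (5954 to 13152) to 892 (243 to 1542). The mitochondrial model of COX1 and its introns (13818 to 26701), which encodes a core subunit of cytochrome c oxidase, fell from 1189 FPKM (859 to 1519) to 34.8 (26.2 to 43.5), a log2 ratio of −5.05 ± 0.27. Falls also included AIM41 (263 to 40.6 FPKM), 1 of 2 models of the polyamine transporter gene TPO4 (24.6 to 1.62 FPKM; the other had 38.4 and 43.2) and YIL169C (14.9 to 1.53 FPKM).

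Among the rises at 39.1 °C, the model of HSP12, which encodes a small membrane-protecting heat shock protein, and YFL013W-A went from 226 FPKM (152 to 301) to 1101 (631 to 1571), a log2 ratio of 2.28 ± 0.39. SPO74, a sporulation gene, rose from 3.29 to 37.6 FPKM, YLL047W from 5.47 to 128 FPKM and YNL337W from 23.6 to 286 FPKM. The short open reading frames YCR095W-A and FYV12 were listed at 0 at 30.0 °C and at 30.3 and 25.7 FPKM at 39.1 °C. Among the 85 tested models without a gene name, 7 were higher and 1 was lower.

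At 39.1 °C ribosome biogenesis genes, which build ribosomes, lay above the range of random lists and ribosomal protein genes below it. The 59 ribosome biogenesis models had a median log2 ratio of 1.11, against −0.42 to 0.20 for matched random lists, and 55 had a ratio above 0. Of them, 5 rose and none fell by the calling rule: UTP18 (3.89 to 30.9 FPKM), UTP5 (17.3 to 73.9), SPB4 (42.9 to 115), RPA34 (1412 to 3441) and YTM1 (193 to 446). Models of the 63 mitochondrial ribosomal proteins lay above their range too, with a median of 0.54 and none called, but the 5 of them in narrow loci stayed within theirs (median 0.75, 88.7th percentile). By contrast, the 104 models of cytosolic ribosomal proteins had a median of −0.71, below their range (−0.42 to 0.03). Of these, 3 fell and none rose: RPP2B (654 to 251 FPKM), RPS19B (718 to 354 FPKM) and the more abundant of the 2 RPL17B models (1065 to 480 FPKM).

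The lists of respiration, purine and amino acid synthesis lay below their ranges at 39.1 °C. The 35 respiratory chain and ATP synthase models had a median of −1.56 (random range −0.52 to 0.23), and 33 had a ratio below 0. ATP1, the alpha subunit of ATP synthase, fell from 111 to 32.9 FPKM and QCR7 of complex III from 524 to 196 FPKM. Purine biosynthesis (15 models, median −1.45) lay below its range, with falls of SHM2 from 66.1 to 11.8 FPKM and ADE2 from 51.5 to 11.7 FPKM; the strain carries the ade2-1 allele. Amino acid biosynthesis (44 models, median −1.11) had 3 falls, SER1, TRP4 and LEU9, and no rise. The 37 proteasome models (median −0.92) had 36 ratios below 0, and PRE4 fell from 224 to 101 FPKM. Glycolysis and fermentation (12 models, median −0.89), the citric acid and glyoxylate cycles (18 models, −0.72), histones (8 models, all in wide loci, −1.21) and ergosterol synthesis (25 models, −0.64) also lay below their ranges. Within ergosterol synthesis the 1 called gene, ERG3, rose from 40.1 to 84.8 FPKM.

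The lists of general stress, trehalose and glycogen, and heat shock chaperone genes lay below their ranges at 39.1 °C. The 15 general stress models had a median of −1.44 and the 16 trehalose and glycogen models a median of −2.17. All models measured for these 2 lists lay in wide loci, and no model of 1 name was called. HSP12, which rose (above), and HXK1 share their models with other genes and were not counted. The model with HXK1 fell from 2803 to 681 FPKM. GLC3, the glycogen branching enzyme gene, had 1 model at 34.3 FPKM at 30.0 °C and 1.23 at 39.1 °C and another at 1779 and 161, and TPS1, the trehalose-6-phosphate synthase gene, had 31.9 and 2.19 FPKM, all with intervals reaching 0. All 24 heat shock chaperone models lay in wide loci and none was called. Their median of −0.67 lay below the range (−0.58 to 0.33), and a pseudocount of 10 put it within (−0.48); HSP42 had 451 and 55.9 FPKM, HSP10 had 5326 and 19994 FPKM, and SSA4 had 43.4 and 27.2 FPKM. A model that holds HSP26 with 2 other genes had 344 and 2206 FPKM, with intervals that reached 0.

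The series title names glutathione, the main thiol antioxidant of yeast. At 39.1 °C the 8 models of its synthesis, breakdown and transport had a median of −0.80, within the random range (−0.86 to 0.74); with a minimum of 20 FPKM it lay below (−0.97). OPT1, a transporter of glutathione and oligopeptides, fell from 70.8 FPKM (49.1 to 92.5) to 25.6 (16.8 to 34.4). The synthesis gene GSH1 had 5.70 and 2.87 FPKM and was not tested, since its mean lay under 5 FPKM. GSH2, the other synthesis gene, had 82.6 and 27.0 FPKM and the reductase gene GLR1 214 and 108 FPKM, not called. Their intervals reached 0 at both temperatures, so no change was detectable with these intervals. The 17 glutathione-dependent enzymes (median −0.61) and the 16 antioxidant enzymes and thioredoxins (−0.04) stayed within their ranges. In the antioxidant list TRR1, thioredoxin reductase, fell from 133 to 64.8 FPKM. Values without a call were 1685 and 2107 FPKM for TRX2, 1243 and 619 for TSA1, 17.1 and 16.1 for SOD2, 149 and 31.7 for the model of CTT1 and NNF2, and 139 and 200 for the model with HSP104. The iron regulon (21 models, median 0.53) and the meiosis and sporulation genes (10 models, 1.17) lay above their ranges with none called, and the unfolded protein response (18 models, −0.72) lay below. With a minimum of 20 FPKM the iron, unfolded protein, citric acid cycle and ergosterol lists were within their ranges, as were the iron (0.16), citric acid cycle (−0.27) and ergosterol (−0.51) lists with no minimum, the unfolded protein list (−0.47) with a pseudocount of 10, and the ergosterol list (−0.37) with models of several names included. Calls at 39.1 °C came from narrow loci in 81 of 84 cases, and a requirement of at least 4-fold left 30 calls. A z test of the log2 ratios from the same intervals kept 52 of the 84 calls and did not keep those of SPO74, YLL047W, TPO4, QCR7, LEU9, ERG3 and TRR1. TRR1, LEU9, ERG3, RPS19B and HXT5 were not called with a pseudocount of 10, nor TRR1, LEU9, QCR7 and RPS19B with centred ratios.

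**Figure D1:**
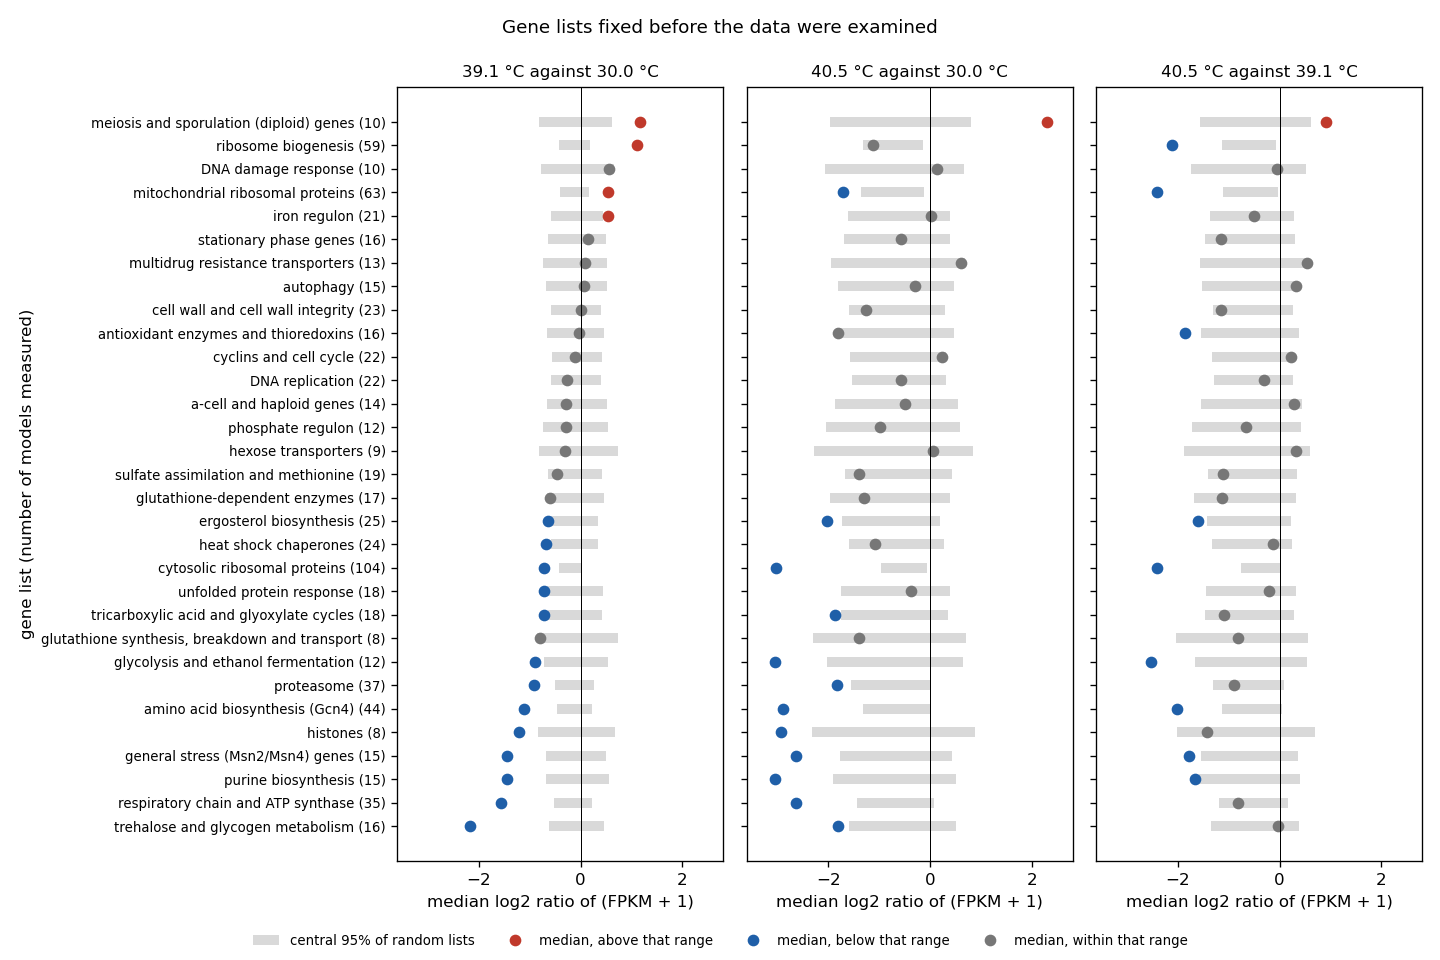
Median log2 ratio of (FPKM + 1) on the horizontal axis for each gene list on the vertical axis, for the 3 comparisons; grey bars span the central range, from the 2.5th percentile upward, of 10000 random lists matched on level, and colours show whether the median lies above, below or within that span. Ribosome biogenesis lies at 1.11 at 39.1 °C against 30.0 °C and at −2.11 at 40.5 °C against 39.1 °C.

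The second comparison set the cultures at 40.5 °C, labelled as no-growth, against those at 30.0 °C. Here 99 models were higher and 168 lower. The median of all tested models was itself −0.58 on the log2 scale, −0.65 in wide loci and −0.14 in narrow loci. With ratios centred on the median of all tested models, 145 were higher and 117 lower, so the larger number of falls depends on the scale. Narrow loci, which held 95 of the rises and 126 of the falls, were not centred on their own median. The largest falls included genes of protein synthesis and of amino acid metabolism. RPL3, a protein of the large ribosomal subunit, went from 3215 FPKM (1558 to 4873) to 75.4 (0 to 255), a log2 ratio of −5.40 ± 1.74, and RPS26A from 12464 to 253 FPKM. HIS4 of histidine synthesis fell from 200.1 to 2.49 FPKM, SHM2 of the folate cycle from 66.1 to 0.632 FPKM (−5.36 ± 0.94), PFY1, which encodes the actin-binding protein profilin, from 1744 to 38.0 FPKM (−5.48 ± 0.56), and the model of SRL1 and YOR248W from 1445 to 25.4 FPKM. PEX11 of peroxisome division was at 38.4 FPKM (18.6 to 58.3) at 30.0 °C and listed at 0 at 40.5 °C. ZPS1 (to 116 FPKM), ADH4 (to 201 FPKM), the model with ZRT1 (to 1194 FPKM) and COX1 (to 36.3 FPKM) were lower than at 30.0 °C here as well.

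The rises at 40.5 °C included genes with little or no signal at 30.0 °C. YER175W-A and YDL242W were listed at 0 at 30.0 °C and at 101 and 86.1 FPKM at 40.5 °C, YCR095W-A reached 85.1 FPKM, and YLL047W rose from 5.47 to 613 FPKM (402 to 824). The sugar transporter family gave HXT13 (1.41 to 65.7 FPKM, log2 ratio 4.79 ± 0.75) and HXT5 (15.9 to 42.2 FPKM) as rises and no fall among 9 models. CAT8, a regulator of growth on carbon sources other than glucose, rose in 1 of its 2 models, from 178 FPKM (0 to 591) to 3649 (1291 to 6007). A model with 9 gene names that include CDC19, the pyruvate kinase gene, rose from 139 to 10161 FPKM, and its reads cannot be given to 1 gene. Single called rises within lists were JEN1, the lactate transporter gene (10.2 to 33.3 FPKM), MMP1, an S-methylmethionine permease gene (8.85 to 38.6), SIT1 (5.10 to 27.9) and FRE2 (log2 ratio 1.52 ± 0.43) of iron uptake, 1 of 2 RAD54 models, of DNA repair (39.3 to 134), ATG36 of peroxisome autophagy (91.4 to 366) and DIT2 of the spore wall (8.88 to 60.0). ISU2 of the iron list (170 to 24.3) and HSP31 of the stationary phase list (158 to 34.4) fell.

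The gene RPL17B (chromosome X, 90786 to 91657) had 2 models in 1 locus that went opposite ways. One fell from 1065 FPKM (806 to 1325) to 21.4 (2.45 to 40.4) and the other rose from 9.30 FPKM (0 to 30.8) to 796 (440 to 1152). EFT2, which encodes elongation factor 2, likewise had 1 model called lower and 1 called higher, with log2 ratios of −4.62 and 3.15. Of 56 gene names with a pair of tested models in 1 narrow locus, 2 had such opposite calls and 28 had ratios of opposite sign. Whether the models of a pair lie on opposite strands was not examined, so 1 of them may hold antisense signal. Models without a name rose in 16 cases and fell in 2.

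Cytosolic ribosomal proteins, the longest list, had the most calls of any list at 40.5 °C, though not the largest share of members called. Their 104 models had a median log2 ratio of −3.03, against −0.96 to −0.06 for matched random lists; 19 fell, 96 had a ratio below 0, and the 1 rise was the second RPL17B model. Falls included RPP2B (654 to 28.6 FPKM) and RPS19B (718 to 83.4). Mitochondrial ribosomal proteins (63 models, median −1.71) lay below their range with 1 fall, MRPL8 (15.1 to 1.38 FPKM), whereas ribosome biogenesis (59 models, −1.13) stayed within its range, with UTP18 higher and RPA49 lower. The 5 mitochondrial ribosomal protein models in narrow loci alone stayed within their range, with a median of −0.45 at 40.5 °C, and all others lay in wide loci. Of 12 glycolysis and fermentation models (median −3.05) 5 fell and none rose: TDH1 went from 265 FPKM (200 to 331) to 7.72 (4.13 to 11.3), ENO2 from 4438 to 288, PDC1 from 835 to 70.5, ADH1 from 1340 to 225 and ADH4 as given above. Amino acid biosynthesis (44 models, median −2.90, 6 falls), purine biosynthesis (15 models, −3.04, 2 falls), the respiratory chain (35 models, −2.63, 2 falls), the proteasome (37 models, −1.83, 6 falls) and ergosterol synthesis (25 models, −2.03, 1 fall) lay below their ranges with no rise. The 10 proteasome models in narrow loci alone stayed within their range at 40.5 °C (median −1.30, 5.51st percentile). RPT5 of the proteasome went from 47.1 to 2.16 FPKM and SER1 of serine synthesis from 95.1 to 6.20 FPKM.

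General stress genes (15 models, median −2.64), histones (8 models, −2.92), trehalose and glycogen genes (16 models, −1.80) and the citric acid and glyoxylate cycles (18 models, −1.87) also lay below at 40.5 °C. None of the first 3 of these lists held a called model with 1 name, and all their measured models lay in wide loci. With a minimum of 20 FPKM the trehalose and glycogen genes (median −0.41) and the citric acid and glyoxylate cycles (−2.03) no longer lay below. Nor did the latter with no minimum (−1.30) or a pseudocount of 10 (−1.02), and the former with models of several names included (−1.56). STF2 and RTC3, both general stress genes, had 1529 and 1240.5 FPKM at 30.0 °C against 9.18 and 14.3 at 40.5 °C, and HTA2, a histone H2A gene, had 1297 against 29.1, with intervals reaching 0. HHF1, the histone model with the highest mean, had 3850 FPKM (981 to 6719) against 8112 (3870 to 12353), not called. Of the 8 histone ratios 6 were below 0 and 2 above. The heat shock chaperones (24 models, −1.08) stayed within their range with none called: SSA4 had 67.7 FPKM, the model with HSP104 137, the model with HSP26 1499 and HSP42 131 at 40.5 °C. The model with HSP12 had an interval of 193 to 413 FPKM, which overlapped that at 30.0 °C. The meiosis and sporulation list (10 models, median 2.29) lay above its range.

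Glutathione genes at 40.5 °C showed 2 falls and no rise among 8 models (median −1.40, within the range of −2.30 to 0.70). DUG1, a peptidase of glutathione breakdown, fell from 164 FPKM (115 to 213) to 36.4 (23.1 to 49.8), a log2 ratio of −2.14 ± 0.34, and OPT1 to 34.3 FPKM (23.2 to 45.5), −1.02 ± 0.32; OPT1 was not called with a pseudocount of 10 (−0.87) or with centred ratios (−0.44). GSH1, not tested, was at 3.84 FPKM, GSH2 at 14.8 and GLR1 at 25.4, with intervals reaching 0. TRR1 fell to 5.74 FPKM (1.44 to 10.0), −4.32 ± 0.51, and a model of 6 genes that includes SOD1 fell from 14567 to 2604 FPKM. The antioxidant list (median −1.80) and the glutathione-dependent enzymes (−1.31) stayed within their ranges, as did the iron (0.02) and unfolded protein (−0.37) lists; the iron list lay above (1.52) with a minimum of 20 FPKM. TSA1 was at 76.7 FPKM and TRX2 at 879, not called, and SOD2 was listed at 0. CLN2, a G1 cyclin gene, had 30.6 FPKM at 30.0 °C and 69.5 at 40.5 °C, not called, and STE4 of the mating pathway fell from 477 to 115 FPKM. Calls in narrow loci numbered 221, and the fold minimum without the intervals would have given 3096. The z test kept 220 of the 267 calls and did not keep those of HIS4, RPS26A, ADH1, CAT8, ATG36, DIT2, SPO74 and UTP18. HIS4 (−5.27), ADH1 (−1.99), TRP4 (−1.24), LEU9 (−1.15), HSP31 (−1.58), RPA49 (−1.58) and the model with HXK1 (−0.78) were not called with centred ratios, given in parentheses. UTP18 and LEU9 were not called with a pseudocount of 10.

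**Figure D2:**
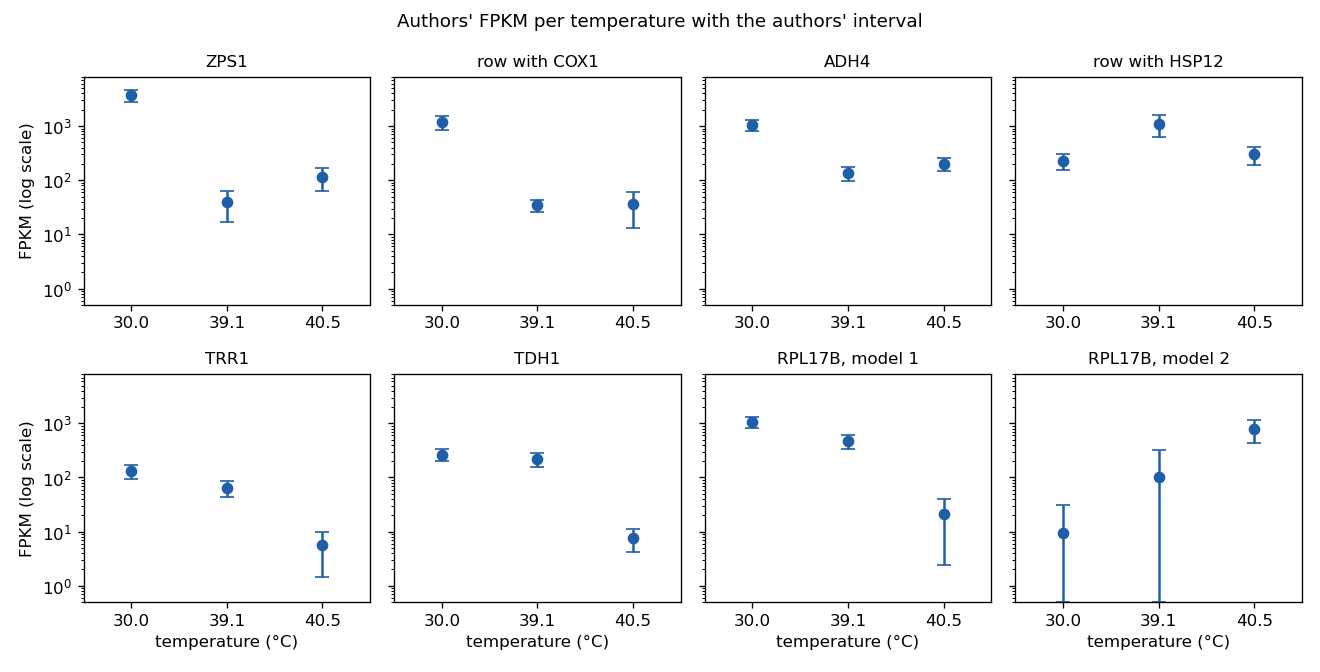
FPKM on a log axis at each temperature in °C for 8 models; points are the authors' pooled values, bars the authors' intervals, and bars that reach the bottom of a panel have a lower bound of 0. ZPS1, COX1 and ADH4 lie far below their 30.0 °C values at both higher temperatures, TDH1 is at 218 FPKM at 39.1 °C and 7.72 at 40.5 °C, and the RPL17B models cross.

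The third comparison set the cultures at 40.5 °C directly against those at 39.1 °C. It gave 56 models higher and 113 lower at 40.5 °C. The median of all models was −0.45 and that of narrow loci −0.13. Centring on the median of all models gave 108 higher and 81 lower. TDH1, a glyceraldehyde-3-phosphate dehydrogenase gene, fell from 218 FPKM (159 to 278) to 7.72 (4.13 to 11.3), a log2 ratio of −4.65 ± 0.36. PFY1 fell from 1038 to 38.0 FPKM, RPS26A from 5926 to 253, COS1, a subtelomeric membrane protein gene, from 54.8 to 1.53 and MIX23 from 136 to 5.45. PEX11 was at 41.6 FPKM at 39.1 °C and listed at 0 at 40.5 °C. Rises were 1 of the 2 CAT8 models (278 to 3649 FPKM, log2 ratio 3.71 ± 2.49; the other had 5.25 and 8.14), HXT2, a high-affinity glucose transporter gene (139 to 1285, 3.20 ± 1.49), HXT13 (8.04 to 65.7), the telomere-binding factor gene RIF2 (154 to 1618) and YOR192C-C (229 to 2126). YDL242W went from 5.80 to 86.1 FPKM, YER175W-A was listed at 0 at 39.1 °C, and ZPS1 was higher at 40.5 °C, at 116 against 39.9 FPKM. The model with HSP12 fell, with a log2 ratio of −1.86 ± 0.40.

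The ribosome biogenesis and ribosomal protein lists lay below their ranges at 40.5 °C against 39.1 °C. Ribosome biogenesis had a median of −2.11, below the range of −1.12 to −0.06, with 57 of 59 ratios below 0 and 4 falls: UTP5 (73.9 to 8.58 FPKM), YTM1 (446 to 190), ROK1 (71.1 to 21.4) and RPA49 (37.4 to 6.28). Its 7 members in narrow loci alone stayed within their range, with a median of −1.23 at the 9.86th percentile. Cytosolic ribosomal proteins had a median of −2.41 with 12 falls and 1 rise, and mitochondrial ribosomal proteins a median of −2.41 with 1 fall. Glycolysis (median −2.52, 3 falls), amino acid biosynthesis (−2.01, 3 falls), purine biosynthesis (−1.66, 1 fall), ergosterol synthesis (−1.60, 1 fall) and general stress genes (−1.77, none called) lay below their ranges. With a pseudocount of 10 glycolysis (−1.25) and purine biosynthesis (−0.83) were within them, as were purine biosynthesis (−1.75) and general stress genes (−2.01) with a minimum of 20 FPKM. The antioxidant list lay below its range (median −1.86), and its 1 call was the fall of TRR1 from 64.8 to 5.74 FPKM. The glutathione list (median −0.81) stayed within its range, with DUG1 lower (104 to 36.4 FPKM). The respiratory chain (−0.81), the proteasome (−0.90), heat shock chaperones (−0.13) and trehalose and glycogen genes (−0.02) stayed within theirs, although heat shock chaperones lay above (0.33) with a minimum of 20 FPKM or with models of several names included. The meiosis and sporulation list lay above, at 0.92, with no model called, and within at a minimum of 20 FPKM. The iron list, within its range here, lay above with a minimum of 20 FPKM (0.82) or none (0.25). With at least 4-fold, 95 calls were left. The z test kept 132 of the 169 calls and did not keep those of CAT8, HXT2, RIF2, YDL242W, ZPS1, RPS26A, RPL3, SHM2 and the second RPL17B model; with centred ratios ROK1, YTM1 and RPL3 were not called.

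The other 11 lists stayed within their ranges in all 3 comparisons under the main settings. Their medians at 39.1 °C against 30.0 °C, 40.5 °C against 30.0 °C and 40.5 °C against 39.1 °C were −0.31, 0.06 and 0.32 for 9 hexose transporters, −0.47, −1.41 and −1.12 for 19 sulfate and methionine genes, and 0.00, −1.25 and −1.15 for 23 cell wall genes. They were −0.11, 0.23 and 0.23 for 22 cyclin and cell cycle genes, −0.27, −0.56 and −0.31 for 22 DNA replication genes, 0.55, 0.14 and −0.05 for 10 DNA damage genes, and −0.29, −0.99 and −0.66 for 12 phosphate genes. For 15 autophagy genes they were 0.08, −0.29 and 0.32, for 14 genes of a-cells and haploid cells −0.28, −0.50 and 0.27, for 16 stationary phase genes 0.15, −0.57 and −1.16, and for 13 multidrug transporters 0.08, 0.62 and 0.54. With no minimum the sulfate list lay below at 39.1 °C (−0.56), the cell wall list below at 40.5 °C against 30.0 °C (−0.99), and the multidrug transporters above at 40.5 °C against 30.0 °C (0.68) and against 39.1 °C (0.54). With a minimum of 20 FPKM the hexose transporters (1.48) and multidrug transporters (1.39) lay above at 40.5 °C against 30.0 °C, as did the latter without models listed at 0 (0.62). With models of several names included the DNA damage list lay above at 39.1 °C (0.70) and the cell wall list below at 40.5 °C against 39.1 °C (−1.26). In that comparison autophagy genes lay above with a pseudocount of 0.1 (0.37), and cyclin and cell cycle genes (0.23) against lists matched on locus class as well. Called at 39.1 °C in these lists were HXT5 (15.9 to 40.9 FPKM, higher), STE4 (477 to 163, lower) and TPO4.

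Models called in both hot cultures against 30.0 °C went mostly the same way: 17 were higher and 38 lower in both, and 3 were called in opposite directions. Independent lists of these sizes, spread over all 5056 tested models, would share 0.744 higher and 1.53 lower models. That yardstick is too low, because most calls lie in the 689 tested models of narrow loci. These held 38 of the rises at 39.1 °C and 95 at 40.5 °C, and 43 and 126 of the falls. Simulated unchanged cultures set against the same 30.0 °C values shared 0.0680 and 0.252 on average. Their noise came from the intervals at 30.0 °C alone, so spread between cultures beyond these was not simulated. Both comparisons use the same 30.0 °C values, which could not be split, so part of the excess may come from them.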

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

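The tests on ribosome biogenesis genes below were chosen after the result was seen. In 3 models the calls against 30.0 °C went opposite ways in the 2 hot cultures, higher at 39.1 °C and lower at 40.5 °C; the difference between the effects was not tested against replicates. MRF1 (chromosome VII, 234538 to 235958), a mitochondrial translation release factor gene, went from 1851 FPKM at 30.0 °C to 4053 at 39.1 °C and 786 at 40.5 °C, a log2 ratio of −2.36 between the hot cultures. KRI1 (chromosome XIV, 54122 to 55897), a gene needed to make the small ribosomal subunit, had 128, 273 and 60.9 FPKM, a ratio of −2.15. YOR283W (chromosome XV, 847453 to 848145), a phosphatase gene, had 136, 331 and 29.7 FPKM, a ratio of −3.44. None of the 3 rises kept its call in a z test of the ratio from the same intervals, the falls of MRF1 (−0.65) and KRI1 (−0.48) were not called with ratios centred on the median, and that of KRI1 (−0.97) was not with a pseudocount of 10. All 3 lie in narrow loci, and MRF1 has a second model in its locus at 7.36, 8.95 and 5.13 FPKM. The strand of the models was not examined, so which of the MRF1 models holds the gene's own transcript is open.

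KRI1 was not on the fixed list of ribosome biogenesis genes, whose median log2 ratio was 1.11 at 39.1 °C. A common scale factor would move all models alike, and the median of all tested models was −0.10 there. The list was flagged for its place above random lists, which such a factor cannot change, so this is no independent test of scaling. Read assignment inside the wide shared loci is argued against for the 7 list members in narrow loci, whose median of 1.28 lay at the 99.3rd percentile of random narrow lists. For the 52 members in wide loci read assignment stays open. Their median of 1.09 lay above the range of random wide lists (−0.45 to 0.18), but 0% of them have intervals above 0 at both temperatures. The growth temperature itself, culture time, which is not given for 30.0 °C, and library batches remain as untested explanations.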

How the results depend on the processing

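The runs on narrow loci, on 1-name models and without models listed at 0, the other ways to build lists, and 3 uses of the intervals for the calls shared by both hot cultures were added after the data were seen. Calls at 39.1 °C against 30.0 °C ranged from 60 to 92 around 84 outside the exceptions that follow, and calls at 40.5 °C against 30.0 °C from 191 to 271 around 267, and at 40.5 °C against 39.1 °C from 139 to 189 around 169. A z test of the ratios from the same intervals (delta method) kept 52 of these 84, 220 of the 267 and 132 of the 169 calls. With at least 4-fold, 30 models were left at 39.1 °C against 30.0 °C, 95 at 40.5 °C against 39.1 °C, and 19 called in both hot cultures, since fewer models pass. The fold minimum without the intervals gave 1621, 3096 and 2614 models and 1135 in both, because wide intervals no longer count. Centring on the median of all tested models turned the balance of higher and lower calls in all 3 comparisons (44 and 38, 145 and 117, 108 and 81). Wide loci had medians of −0.13, −0.65 and −0.51. Narrow loci, which hold most calls, had medians of 0.05, −0.14 and −0.13, and no run centred on these. The cause of the global shift was not tested. Centring cannot move a list against its random lists and was left out of the next counts. Lists kept their position in 614 of 651 list results, passed out of their range in 17 and moved into it in 20, and none changed sides. Among them, the iron regulon lay above at 40.5 °C with a minimum of 20 FPKM (median 1.52) and heat shock chaperones above at 40.5 °C against 39.1 °C (0.33), while both citric acid cycle results below their ranges moved into them (−0.77 and −2.03). Named models with a call kept it in 2505 of 2660 results and lost it in 155. The losses came with at least 4-fold (65), the z test (45), centring (35) and a pseudocount of 10 (10). No other setting could take a call away: each loosened the rule, or models it left out were not counted. The share kept therefore overstates how stable the calls were. Of 9938 results without a call 580 gained one, 556 of them with the fold minimum alone, and 39 changed sign only because centring shifts all ratios alike. No paired analysis was possible because the table gives 1 pooled value per temperature. Leaving out a library, the block, limma variants, fits of single pairs of groups and tests of lists with an estimated correlation could not be run for the same reason. Unknown depth and intervals reaching 0 in 96.2% of wide models at 30.0 °C limit what can be called.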

Other observations

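All tests in this part were chosen after the results were seen. Genes near chromosome ends differed from tested genes of the same level and locus class (narrow or wide). The 189 tested models with 1 name within 30 kb of a chromosome end had a median log2 ratio of 0.05 at 40.5 °C against 30.0 °C, where matched random lists gave −0.77 to −0.12; 31 were called higher and 17 lower, and 98 ratios were above 0 and 91 below. Among all 5056 tested models 99 were called higher and 168 lower at 40.5 °C, mostly in narrow loci. For the 189 models at 39.1 °C the median was 0.20, against −0.19 to 0.15. The median lay at the 99.9th percentile at 40.5 °C, an offset far smaller than the largest rises. Of the 8 largest rises only 2 are among the 189 models, YDL242W and YCR095W-A, and without them the other 187 lay at the 99.8th percentile. The set holds models with 1 name found in R64, so models without a name were not tested here. It was not a rise of every family there. The 7 COS genes, a subtelomeric family of membrane proteins, had a median of −1.81, with COS1, COS6 and COS7 lower and none higher. The standard error of the mean of their ratios was 0.72, a spread over genes and not over cultures. Near-identical copies can share their reads, so these genes are not independent.

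ZPS1 and ADH4, targets of Zap1, the activator of genes for zinc shortage, fell in both hot cultures. So did a model of 5 genes that include the target ZRT1, whose own level is not shown. Lower Zap1 activity may account for this, but the rest of the regulon left it open. The median of 8 other tested targets was −0.22 at 39.1 °C, at the 36.0th percentile of matched lists. At 40.5 °C it was −1.39, at the 19.4th percentile. Of these targets, 5 had a ratio below 0 at 39.1 °C and 3 above, and none was called in either hot culture. For 7 of them the lower bound at 30.0 °C was 0, so members going both ways with such intervals decide nothing. A first form of the prediction took any percentile above the 2.5th as evidence against and was replaced for that reason after its result was seen.

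The COX1 model fell in both hot cultures, and of 42 mitochondrial models 38 were listed at 0 at all temperatures. A common scale factor would move all models alike, and COX1 had a log2 ratio at 39.1 °C of −4.95 (SE 0.27) relative to the median of all tested models. COX1 was picked for its large fall, so this is no independent test of scaling. Loss of the mitochondrial genome from every cell at 39.1 °C would leave no COX1 signal, and the lower bound was 26.2 FPKM. That value is pooled over 3 libraries, and the source of the remaining reads was not tested. The bound therefore does not decide whether the genome was kept, and loss in single libraries stays open. A lower recovery of mitochondrial transcripts stays open, because only 1 other model, 21S ribosomal RNA, was above 5 FPKM at 30.0 °C. It went from 11.2 FPKM to a listing at 0. COX3 went from 2.39 FPKM to a listing at 0 in both hot cultures. The model with COB was listed at 0 at 30.0 °C and 39.1 °C and at 3.10 FPKM at 40.5 °C. A partial loss of the genome and the growth temperature are untested.

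Models without a gene name were higher in the hot cultures. Their median FPKM was 28.9 at 30.0 °C, 59.9 at 39.1 °C and 128 at 40.5 °C, and of the 26 in narrow loci 25 overlap no R64 gene and 20 lie within 30 kb of a chromosome end. Reads spread evenly over the genome would lift every model alike and are argued against as the source of the whole rise. The 26 rose by a median of 69.2 FPKM. Of 331 named models of like width, 58.6% had an upper bound at 40.5 °C below that (36.9% below the lower quartile of the rise). A lower even background that gave part of the rise is not excluded. The comparison with named models replaced a first test on models listed at 0, which may be failed estimates, after the result of that test was seen. Limits of the new comparison were also chosen after its values had been seen. Scaling is argued against by the median log2 ratio of 2.11 of the models without a name, where named models of the same level and locus class gave −1.21 to −0.16. Assembly from the hot libraries stays open: 88.2% were highest in a hot culture, and the table does not say which library a model came from. The growth temperature, and whether the position near chromosome ends matters for these models, are untested.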
